A study of Mus musculus with 102 samples.

How the data were processed

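RNA was measured in microglia sorted from the lumbar spinal cord of wild type (WT) mice and of ABC-imKO mice (KO), in which Abca1 and Abcg1 can be deleted in microglia by an inducible Cre recombinase. Per the labels' protocols, cells were collected by flow cytometry straight into lysis buffer. Polyadenylated RNA was primed with oligo(dT) and amplified by PCR, Nextera XT libraries were made from it, and read pairs of 50 bases were sequenced on a NovaSeq. Mice were naive, or had received cisplatin on days 1 and 3 followed on day 7 by an intrathecal injection of saline or of AIBP, a protein that binds apolipoprotein A-I. The naive groups had no injection, so every comparison of naive with cisplatin saline also holds the intrathecal injection. The labels give 6 groups: 3 biological samples in each of 5 groups and 2 (7 and 9) in WT cisplatin AIBP. Each biological sample was sequenced as 3 technical replicates on 2 lanes, which makes 51 libraries and 102 runs.

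Per the submitters' processing notes, reads were handled with bcl2fastq, FastQC 0.11.17, MultiQC 1.7, STAR 2.6.0a and DESeq2 on the mouse build GRCm38; the counting tool and the strand setting were not given in the sources used here. The authors deposited a table of raw counts (unit: counts) for 53715 genes and 102 runs. A normalized table of 18856 genes, also deposited by the authors, holds signal: within each of the 102 runs, raw count over normalized value was constant (relative tolerance 1e-09), with factors from 0.437 to 1.62, so it is raw counts divided by one size factor per run. The raw counts were used for every test. Gene IDs were named from GENCODE mouse release M21 (53620 named, 95 left without a symbol), and positions are on GRCm38.

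Runs held 4.51 to 15.2 M counts (M for mega, median 11.3), libraries 9.04 to 30.4 M (median 22.5) and biological samples 45.1 to 76.6 M (median 63.1). The 2 lanes of a library differed little beyond counting error (chi-square per degree of freedom 1.22 to 1.35), whereas 2 technical replicates of a biological sample differed far more (42.6 to 316, median 104). Among 6795 genes at 20 CPM (counts scaled by library size, edgeR) or more, the median SD of log2 CPM was 0.507 between technical replicates (single libraries) and 0.334 between biological samples of a group (each a sum of 3 libraries). Counts of the 6 runs of a biological sample were therefore summed, and the 17 biological samples were the units of every test. The labels do not say whether a numbered sample is 1 mouse or a pool, so p-values measure the spread between these samples. Sums of 3 libraries carry technical spread too, so the spread between the samples themselves was smaller than 0.334. In a limma-voom fit the correlation of technical replicates within a sample was only 0.0893, so little of the spread among libraries of a group lay between samples. Per sample, 18791 to 21467 genes were detected, 1.53 to 3.04% of counts were mitochondrial and the 10 most abundant genes held 9.21 to 13.6%.

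Groups were compared with edgeR 4.0.16 (R 4.3.3): TMM scaling (factors 0.885 to 1.11), filterByExpr by group (20461 genes tested), the quasi-likelihood F test (glmQLFit, glmQLFTest) with a group means model over all 17 samples (11 residual degrees of freedom, biological coefficient of variation 0.922), and Benjamini-Hochberg (BH) adjustment over all genes tested with a threshold of 0.05. All tests were two-sided and every adjusted p of a gene comes from this model. There were 10 contrasts, 2 of them interactions. CPM values are means ± SD over biological samples with TMM-scaled library sizes, and log2 fold changes are given ± SE. Against a group with a count of 0 in every sample a fold is a lower bound, set at 3 counts over the group, and against 1 to 3 counts it is a ratio with its 95% counting interval.

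Gene lists of microglial states, cholesterol handling, signalling, stress and metabolism, and markers of other cell types that a sort could hold, 30 in all, were tested with camera in limma 3.58.1 (preset correlation 0.01, BH over the 30 lists of a contrast) and again with an estimated correlation. The preset test took the counts of the fit and the other took log2 CPM (prior count 2). A list call lost with an estimated correlation may therefore also reflect the input. A list's adjusted p comes from camera. Counts of members are given over all genes tested and adjusted over the list alone. Sharing between contrasts was given as Pearson r across genes, which are not independent replicates. Where contrasts share a group, r was set beside 20 simulations in which no group differed.

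Named genes followed a rule. Abca1 and Abcg1 come first in every sample. In each contrast the 10 largest rises and 10 largest falls come next, among called genes with a mean of at least 10 CPM in the higher group and a symbol other than a gene model, clone or pseudogene. Up to 4 members per list with the smallest p follow, over all genes or else over the list alone. Where fewer than 5 genes passed, the 5 smallest p were selected as values that did not pass. Not every gene that the rule selected is given below. Groups, contrasts, tests, lists, the rule and the first set of alternatives were fixed before the data were examined.

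The test was checked on simulated counts with 200 genes changed. A change of 2-fold was recovered for 7, 1.5 and 9% of genes, and one of 4-fold for 77.5, 67 and 77.5%, in the designs of the cisplatin effect in WT, the AIBP effect in WT and the knockout effect in naive samples. With 200 genes changed at this spread, changes of about 2-fold in single genes mostly went uncalled. Where more genes change, BH adjustment is less strict. Of the 595 genes called for cisplatin in WT, 430 changed by at least 2-fold and the others by less. camera called a list raised 2-fold (adjusted p = 2.07e-36) and 0 of 20 unchanged lists. Each gene was drawn independently there, so this does not test false calls of lists whose members move together.

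Alternatives were RLE scaling, no filter on low counts, a stricter filter, DESeq2 1.42.0, limma-voom, a fit of the compared groups only, technical replicates as libraries with their correlation (with and without a replicate block), each technical replicate number left out, each lane alone, the share of genes detected as a covariate, sample number as a block between genotypes, and each sample left out in turn. Added after the data were seen were an offset for transcript length and GC content, 51 libraries or 102 runs taken as independent, the genes of the normalized table only, a fit without the samples labelled KO cisplatin AIBP, samples 5 and 6 of WT cisplatin saline left out together, and the immediate early list score as a covariate. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. No sample was left out.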

Results

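Lumbar spinal microglia of WT and ABC-imKO mice were compared untreated, after cisplatin, and after cisplatin with intrathecal AIBP. The floxed genes encode the cholesterol exporters ABCA1 (chromosome 4, 53030787 to 53159895) and ABCG1 (chromosome 17, 31057675 to 31117988). Abca1 stood at 87.3, 114 and 106 CPM in the WT naive samples, 61.8, 76.1 and 60.4 in WT cisplatin saline and 41.1 and 45.6 in WT cisplatin AIBP. In KO it stood at 105, 78.6 and 66.1 CPM in naive, 98.5, 56.6 and 59.7 in cisplatin saline and 65.7, 59.6 and 32.6 in the samples labelled KO cisplatin AIBP. Abcg1 stood at 160, 91.7 and 107 CPM in WT naive, 42.7, 56.4 and 65.7 in WT cisplatin saline, and 36.2 and 63.1 in WT cisplatin AIBP. In KO it stood at 41.6, 66.4 and 56.0 in naive, 68.4, 50.9 and 54.1 in cisplatin saline and 44.6, 25.6 and 59.0 in the samples labelled KO cisplatin AIBP. Between naive KO and naive WT, neither passed the test (Abca1 log2 fold change -0.30 ± 0.28, adjusted p = 0.947; Abcg1 -1.13 ± 0.32, adjusted p = 0.789). Gene-level counts include exons outside the floxed ones, so these values do not measure the deletion.

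**Figure D1:**
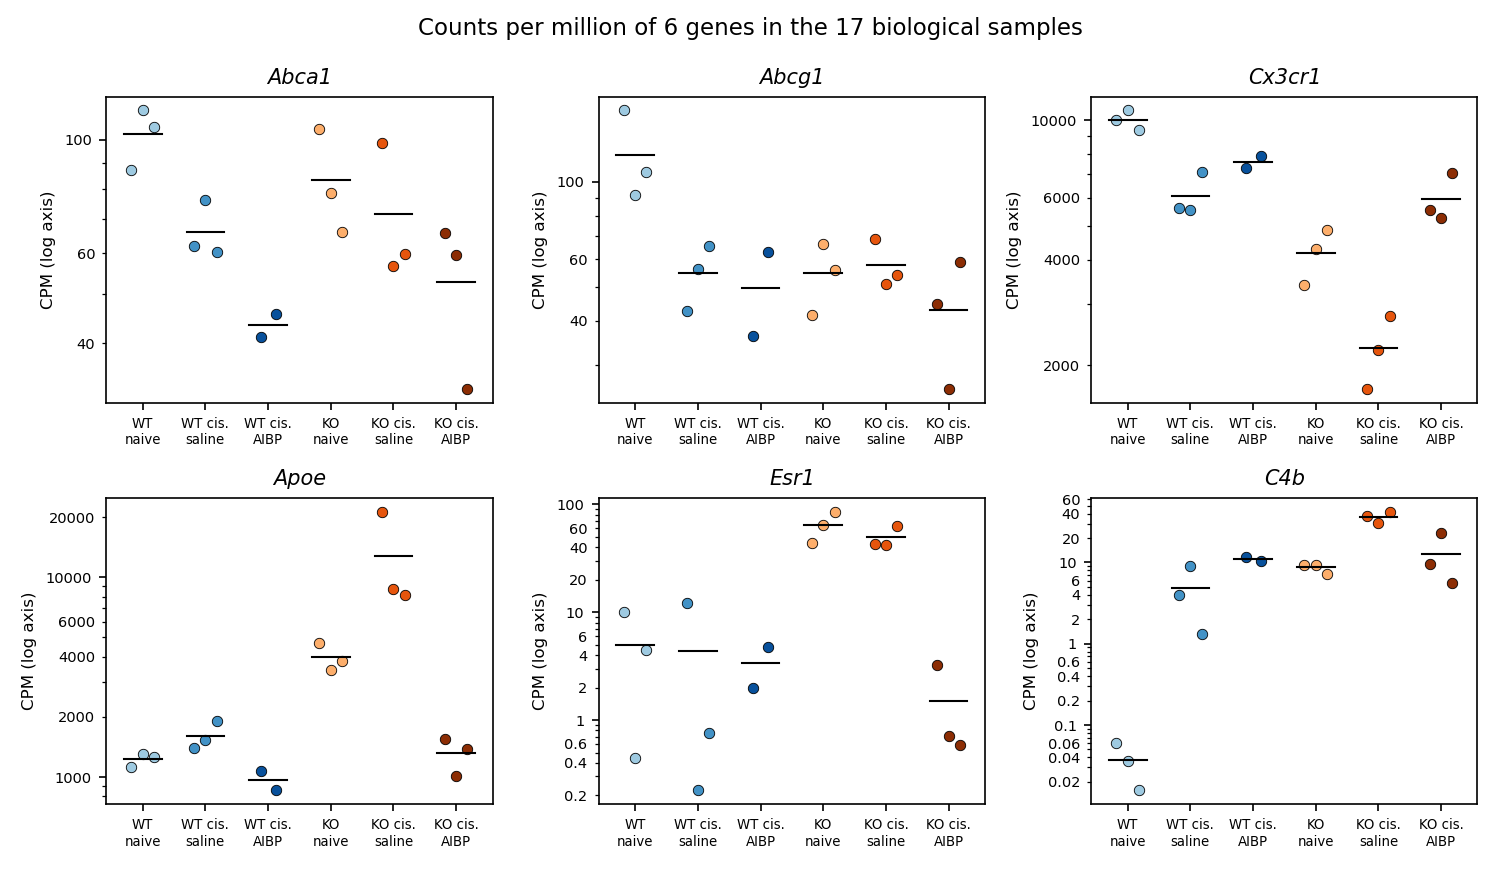
CPM per biological sample (log axis) of Abca1, Abcg1, Cx3cr1, Apoe, Esr1 and C4b in the 6 groups, where cis. stands for cisplatin, points are samples and bars are group means. The samples labelled KO cisplatin AIBP lie at 5250 to 7078 CPM for Cx3cr1, 1007 to 1541 for Apoe and 0.589 to 3.23 for Esr1, against 1718 to 4871, 3421 to 21278 and 42.3 to 85.6 in the other KO samples.

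In WT, cisplatin was followed by falls of 6 of 18 homeostatic microglia genes and rises of 62 of 83 ribosomal protein genes (adjusted p = 0.17 and adjusted p = 0.072 for the lists with an estimated correlation). P2ry12, the purinergic receptor that guides microglial processes, fell from 6604 ± 838 CPM in naive to 1869 ± 798 after cisplatin and saline (n = 3 each, log2 fold change -1.82 ± 0.33, adjusted p = 0.0094). Spp1, which encodes osteopontin, rose from 33.3 ± 49 to 2234 ± 1506 CPM (6.07 ± 1.20, adjusted p = 0.0152), and the scavenger receptor Msr1 rose from 2.45 ± 1.2 to 118 ± 93 (5.59 ± 0.94, adjusted p = 0.0067). Rpl38, a protein of the large ribosomal subunit, rose from 21.2 ± 2.1 to 92.6 ± 23 CPM (2.12 ± 0.21, adjusted p = 0.00034). Of 20461 genes tested, 595 passed, 400 higher and 195 lower, 430 of them by at least 2-fold.

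Among the 18 homeostatic microglia genes, 6 fell, 0 rose and 12 did not pass (16 lower when adjusted over the list alone, median log2 fold change -0.77). They include P2ry13 (-0.97), Gpr34 (-1.54) and Cst3, the protease inhibitor cystatin C, which fell from 31922 ± 4198 to 14741 ± 4173 CPM. The list was lower by camera (adjusted p = 1.4e-15), but not with the estimated value (adjusted p = 0.17 with an estimated correlation). Disease-associated microglia genes moved both ways. Of 23, 5 rose, with the cystatin Cst7 (2.90), Cd63 (1.43) and the lipase gene Lpl (2.23) among them. Another 3 fell (10 higher and 4 lower when adjusted over the list alone, adjusted p = 0.037, adjusted p = 0.49 with an estimated correlation). As mean log2 CPM above WT naive, this list stood at 1.19 and 1.41 in WT cisplatin saline 5 and 6, where monocyte scores were 5.39 and 5.16, and at 0.117 in sample 4, and with that sample alone against the naive samples, its spread taken from other groups, it was not called (adjusted p = 0.73). In cholesterol uptake and storage, 2 of 22 rose, Msr1 and Cd36 (4.22), and the list was not called (adjusted p = 0.2). Cholesterol synthesis held 1 of 24 members higher, Hsd17b7 (3.50; 2 when adjusted over the list alone), with a median of 0.58, and was called both ways (adjusted p = 2.4e-05, adjusted p = 0.03 with an estimated correlation). Of the proliferation list 5 of 18 rose (11 when adjusted over the list alone, median 2.3, adjusted p = 2.6e-12, adjusted p = 0.072 with an estimated correlation). Among them were the replication helicase genes Mcm2 (3.34), Mcm3 (1.54) and Mcm5 (2.78) and the topoisomerase Top2a (4.16).

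Ribosomal protein transcripts rose most broadly, 62 of 83 with 0 lower (75 when adjusted over the list alone, median 1.1, adjusted p = 1.5e-88, adjusted p = 0.072 with an estimated correlation). Oxidative phosphorylation had 8 of 26 higher, such as Ndufa4 (1.07) and Cox5b (1.24), and 19 when adjusted over the list alone (median 0.64, adjusted p = 7.3e-16, adjusted p = 0.24 with an estimated correlation). Glycolysis had 5 of 15 higher, with Gapdh (1.57), Pkm (1.72) and Ldha (1.52), and 8 over the list alone (adjusted p = 1.9e-05, adjusted p = 0.37 with an estimated correlation, adjusted p = 0.063 without samples 5 and 6, 1 sample left). ER stress also had 5 of 15 higher, the chaperone genes Sdf2l1 (1.38), Calr (1.21), Hsp90b1 (0.83) and Pdia6 (0.91) among them, and 7 over the list alone (adjusted p = 1.6e-05, adjusted p = 0.37 with an estimated correlation). In the lysosome list the hydrolase genes went apart: Hexa (-1.12) and Ctsd (-1.29) fell, while Gla (2.63) and Ctsc (1.29) rose, and the list was not called (adjusted p = 0.058). The chemokine Ccl12 rose from 254 ± 133 to 1582 ± 971 CPM (2.64 ± 0.46, adjusted p = 0.00781), the only member of 28 in the inflammatory list to pass (adjusted p = 0.092 for the list). Single members passed in the interferon (Ifitm3, 2.40), complement (C5ar1, 1.21), TLR (Irak2, -1.11), mitochondrially encoded (mt-Nd1, 0.82) and astrocyte (Slc1a3, -1.55) lists, and Cd74 (2.44) and H2-K1 (-0.67) in antigen presentation. Those 6 lists were not called (adjusted p = 0.33, 0.29, 0.17, 0.2, 0.061 and 0.99), nor were pain-associated genes (0.07), LXR targets (0.73), p53 (0.66) or immediate early genes (0.29). Other large changes included rises of Lgals1 (4.03), Ifi207 (4.44), Brip1 (4.61) and Cd244a (3.83) and falls of Prkce (-3.67), Fcrl1 (-2.72), Prkch (-2.65), Trp53i11 (-2.60) and Upk1b (-2.06).

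Transcripts of other myeloid cells differed among these samples. Ccr2, the monocyte chemokine receptor, stood at 95.3 and 62.8 CPM in WT cisplatin saline 5 and 6 and at 10.2 or less in the other 15 samples. The lists of monocytes (median 4.2, adjusted p = 0.0021), of perivascular and border macrophages (median 6.5, adjusted p = 0.0088) and of oligodendrocytes (median -0.55, adjusted p = 0.04) were called with 0 members passing over all genes. None was kept (adjusted p = 0.37 with an estimated correlation for each). The monocyte score of WT cisplatin saline 4 lay within the naive range, so the rise of the monocyte list in WT came from samples 5 and 6. Neutrophils (0.19), T and NK cells (0.99), B cells (0.55), oligodendrocyte precursors (0.99), neurons (0.99) and endothelial cells (0.42) were not called. The rule for named genes still selected the neutrophil markers Mmp8 and S100a8. Mmp8 held 1 count over WT naive and 1333 over WT cisplatin saline (ratio 1277, interval 229 to 50465). S100a8 held 0 and 266 counts (at least 84.9-fold higher), so neutrophil transcripts are not excluded. Clec4n, a lectin receptor of myeloid cells and the largest rise (9.06 ± 2.16, adjusted p = 0.0368), stood at 58.3 and 102 CPM in samples 5 and 6 and had a log2 fold change of -0.30 without them. The count of 595 became 7 without both samples, where 1 sample is left in the group, its spread is taken from the other groups and a loss of calls follows from that size too. It was 149 and 220 without 5 or 6 alone, and 221, 279 and 337 without WT naive 1, 2 or 3. It was 977 under a stricter filter, 1795 by DESeq2, 69 in a fit of these 2 groups alone, 287 and 381 without technical replicate 2 or 3, and 1840 with technical replicates as libraries and their number as a replicate block.

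**Figure D2:**
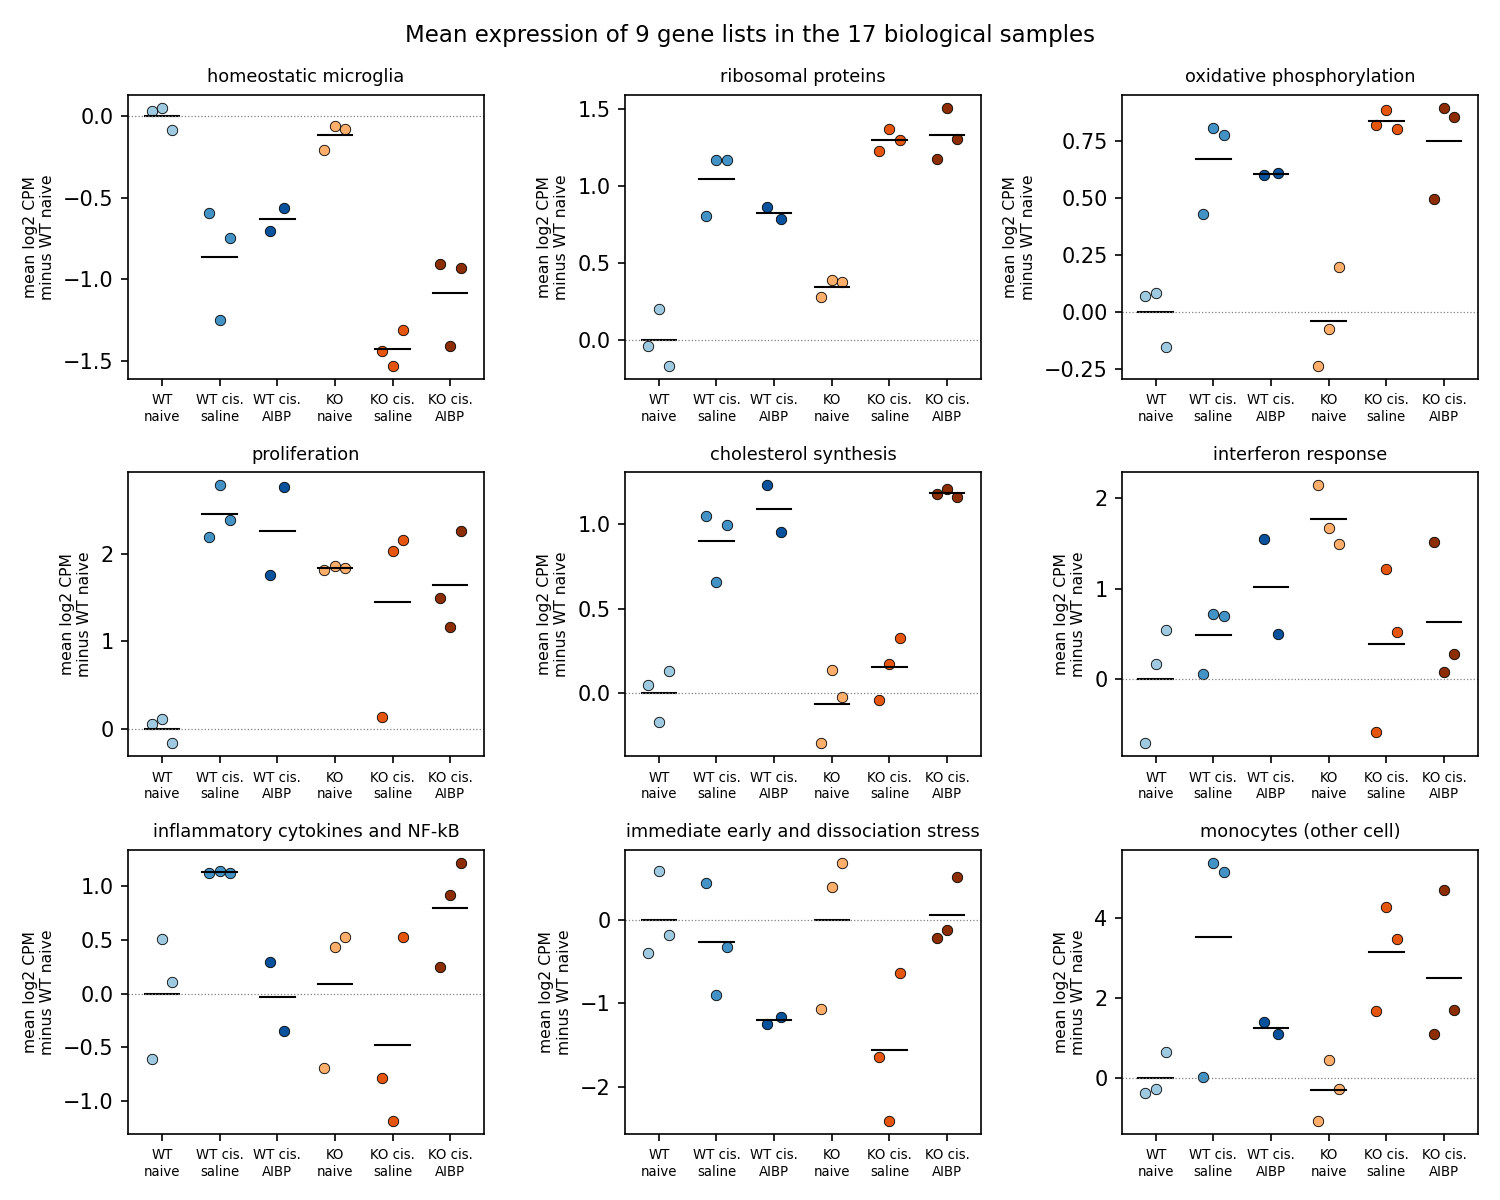
Mean log2 CPM of 9 gene lists per biological sample, as the difference from the mean of the WT naive samples; points are samples, bars are group means and cis. stands for cisplatin. The 6 cisplatin saline samples lie at 0.808 to 1.37 for ribosomal proteins, and the 6 naive samples at 0.389 or less.

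In KO, cisplatin was followed by falls of 13 of 18 homeostatic genes and of 7 of 23 immediate early and dissociation stress genes (adjusted p = 0.13 and adjusted p = 0.42 for the lists with an estimated correlation). Cst3 fell from 29414 ± 2221 to 7365 ± 1262 CPM (-2 ± 0.21, adjusted p = 0.000316). Tmem119 fell from 5038 ± 416 to 1886 ± 319 (-1.42 ± 0.17, adjusted p = 0.000641) and the heat shock gene Hspa1b fell from 144 ± 6.7 to 9.70 ± 6.3 (-3.89 ± 0.62, adjusted p = 0.00291; n = 3 each). Lrg1, which encodes a secreted glycoprotein, rose from 0.162 ± 0.18 to 69.1 ± 35 CPM (8.71 ± 1.06, adjusted p = 0.000596), and fibronectin (Fn1) from 9.17 ± 6.7 to 817 ± 239 (6.48 ± 1.43, adjusted p = 0.0184). Apoe, the main apolipoprotein of brain lipid transport, rose from 3971 ± 653 to 12711 ± 7426 CPM (1.68 ± 0.30, adjusted p = 0.00602). In all, 903 genes passed, 496 higher and 407 lower, 676 of them by at least 2-fold.

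Of the homeostatic list 13 of 18 fell and 0 rose (18 lower when adjusted over the list alone, median -1.3, adjusted p = 6.2e-32, adjusted p = 0.13 with an estimated correlation). Olfml3 (-1.65), Gpr34 (-2.03) and P2ry12 (-2.01) were among them. Ribosomal proteins had 59 of 83 higher (73 over the list alone, median 1, adjusted p = 6.1e-74). Oxidative phosphorylation had 13 of 26 (22 over the list alone, median 0.82, adjusted p = 2.8e-25). With an estimated correlation each had adjusted p = 0.13. Glycolysis had 4 of 15 higher (7 over the list alone, adjusted p = 0.00075, adjusted p = 0.42 with an estimated correlation). In the immediate early and dissociation stress list 7 of 23 fell (10 over the list alone, median -1.4, adjusted p = 1.4e-11, adjusted p = 0.42 with an estimated correlation), among them Hspa1a (-3.42), Hsp90aa1 (-1.84) and Rhob (-1.33). Disease-associated genes again split, with 4 of 23 higher, among them Apoe and Cd63 (1.79), and 3 lower, among them Ctsd (-1.51) and the lipid-sensing receptor Trem2 (-1.12), and the list was not called (adjusted p = 0.93). Antigen presentation had 3 of 14 lower, H2-K1 (-0.80), H2-D1 (-0.57) and Psmb9 (-0.94), and 5 over the list alone (adjusted p = 0.027, adjusted p = 0.46 with an estimated correlation). The interferon list had 0 of 21 lower over all genes and 4 over the list alone (median -1.1, adjusted p = 0.00019, adjusted p = 0.42 with an estimated correlation).

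Further rises in KO were Xdh (6.62), the decoy receptor Il1r2 (6.16), Cd300lf (5.40), Ecm1 (5.13), Adamtsl4 (5.08) and Msr1 (4.92). The transporter Slc10a6, at 2 counts over the naive samples, had a ratio of 1041 (interval 288 to 8604). Falls included Hspb1 (-4.24), Zmat1 (-4.11), Kcnk12 (-3.46), Usp11 (-3.42), St8sia6 (-3.38), Gp9 (-3.34) and S1pr1 (-3.37), the receptor for sphingosine 1-phosphate. The monocyte list was called (median 4.2, adjusted p = 0.0056, adjusted p = 0.42 with an estimated correlation), with Fn1 as its only member passing and 4 over the list alone. Astrocyte markers were lower (0 of 8, 3 over the list alone, median -0.85, adjusted p = 0.027, adjusted p = 0.42 with an estimated correlation), as were lysosome (3 of 23 lower and 2 higher, adjusted p = 0.0056, adjusted p = 0.58 with an estimated correlation) and pain-associated genes (2 of 19 lower, adjusted p = 0.027, adjusted p = 0.42 with an estimated correlation). Mitochondrially encoded genes were higher (1 of 20, adjusted p = 0.032, adjusted p = 0.58 with an estimated correlation). Ccr2 stayed at 6.74 CPM or less in KO cisplatin saline, while Chil3, another monocyte gene, stood at 116, 106 and 76.9 CPM there. Without KO naive 1 or 2 the count was 512 or 394, and without KO cisplatin saline 4 or 5 it was 563 or 366. It was 1389 under the stricter filter, 2193 by DESeq2, 584 with these 2 groups alone, 2356 with the replicate block and 95 with the immediate early score as a covariate. Under that covariate the inflammatory list turned from lower (adjusted p = 0.046, adjusted p = 0.57 with an estimated correlation) to higher (adjusted p = 0.02).

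The cisplatin effects in WT and KO shared many genes: 245 were higher and 87 lower in both and 0 in opposite directions, where independent lists of those sizes would share 9.7 and 3.88. Of the 400 genes higher in WT, 388 had a positive fold change in KO, and of the 195 lower, 191 a negative one. Across the 8570 genes at 10 CPM or more the fold changes had r = 0.641, and across all 20461 tested r = 0.115 (genes are not independent replicates). No gene's cisplatin effect differed between genotypes past the threshold (0 by edgeR, 1561 at an unadjusted p under 0.05, 187 by DESeq2, 1 by limma-voom). The smallest p belonged to Olfml3, at 3328 and 3637 CPM in WT and 3971 and 1261 in KO before and after cisplatin (interaction -1.78 ± 0.27, adjusted p = 0.16). It was followed by Hspa1b (-5.20 ± 0.82, adjusted p = 0.16), Hsp90aa1 (-2.11 ± 0.36, adjusted p = 0.237) and Klf13 (2.23 ± 0.41, adjusted p = 0.349).

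**Figure D3:**
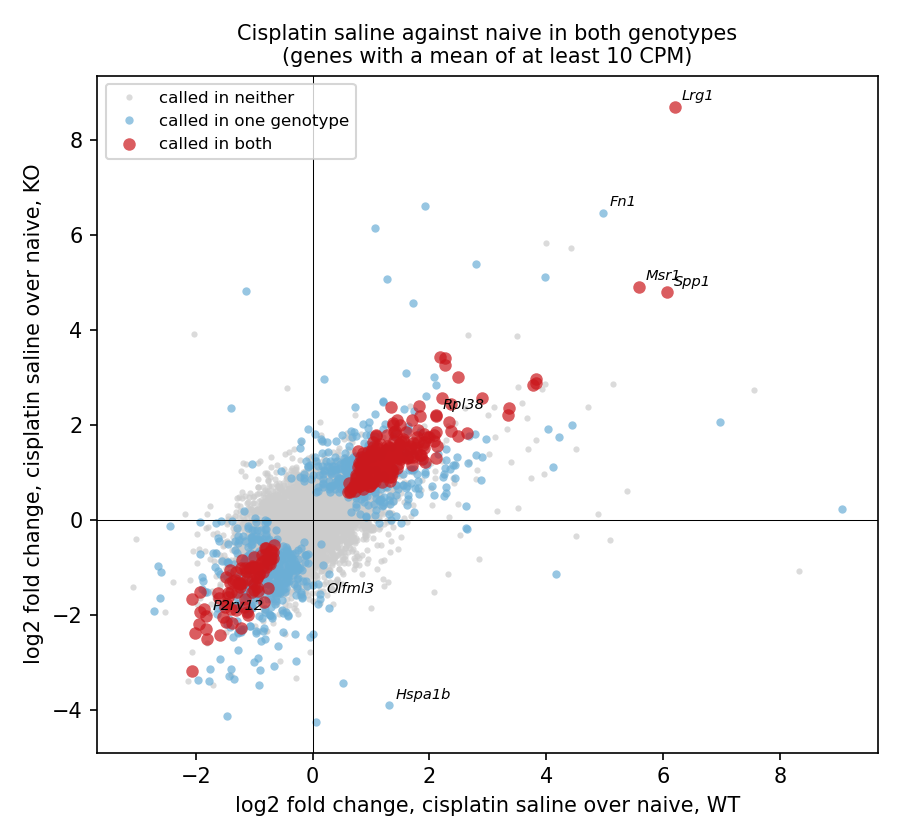
Log2 fold change after cisplatin in KO (vertical axis) against WT (horizontal axis) for 8570 genes at 10 CPM or more; each point is a gene, coloured by whether it passed in both (325), in 1 (750) or in neither. Most genes passing in both lie along the diagonal, such as Spp1, Msr1 and Rpl38 above 0 and P2ry12 below it.

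In naive mice, 1 gene differed between genotypes, the complement gene C4b (chromosome 17, 34728380 to 34743882). It stood at 0.0374 ± 0.022 CPM in WT, 6 counts in all, and 8.69 ± 1.2 in KO (7.83 ± 0.85, adjusted p = 0.00365, n = 3 each). C4b stood at 1.32 to 42.2 CPM in every other sample of both genotypes, so the low group was WT naive. Cx3cr1, the fractalkine receptor whose promoter drives the Cre recombinase per the labels, stood at 9998 ± 653 CPM in WT and 4186 ± 743 in KO (-1.26 ± 0.19, adjusted p = 0.0757). Apoe stood at 1227 ± 94 and 3971 ± 653 (1.69 ± 0.30, adjusted p = 0.243). Neither passed.

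Interferon genes had 0 of 21 passing over all genes and 6 higher when adjusted over the list alone (median 1.7, adjusted p = 2.3e-22, adjusted p = 0.23 with an estimated correlation). Ifi27l2a stood at 7.54 ± 2.9 CPM in WT and 50.4 ± 16 in KO and Oas1a at 6.5 ± 1.2 and 27.9 ± 6.6. Disease-associated genes had 5 of 23 higher over the list alone, with Axl at 57.9 ± 11 and 143 ± 23 CPM (median 0.48, adjusted p = 1.5e-07, adjusted p = 0.23 with an estimated correlation). The lists of ribosomal proteins (9 of 83 over the list alone, median 0.33, adjusted p = 1.2e-20), proliferation (1 of 18, median 1.1, adjusted p = 7.2e-06), LXR targets (1 of 14, adjusted p = 0.018) and antigen presentation (0 of 14, adjusted p = 0.0013) were also higher. That of oligodendrocytes was lower (0 of 8, adjusted p = 0.011). None was kept (adjusted p = 0.38 with an estimated correlation, 0.31 for proliferation). Neither cholesterol synthesis (median -0.08, adjusted p = 0.18) nor inflammatory cytokines (-0.10, adjusted p = 0.92) differed past the threshold. At an unadjusted p under 0.05 there were 1220 genes, and the count of called genes was 170 by DESeq2, 5 without a filter and 16 with the replicate block. C4b lost its call by limma-voom, in a fit of the 2 groups alone, without technical replicate 1 or 3, with sample number as a block and without WT naive 2, where 0 genes passed (2 without WT naive 3).

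After cisplatin and saline, KO microglia held more Apoe and less Cx3cr1 and Olfml3 than WT. Apoe (chromosome 7, 19696109 to 19699188) stood at 1612 ± 256 CPM in WT and 12711 ± 7426 in KO (2.98 ± 0.32, adjusted p = 0.00318). Cx3cr1 (chromosome 9, 119901616 to 120069879) stood at 6081 ± 886 and 2235 ± 527 (-1.44 ± 0.19, adjusted p = 0.0106). Its promoter drives the Cre recombinase in KO per the labels, so its lower level is not read as a homeostatic change. Olfml3 stood at 3637 ± 408 and 1261 ± 343 (-1.53 ± 0.20, adjusted p = 0.0106; n = 3 each). The transcription factor Klf13 (2.08), Il15ra (1.71) and Lifr (1.26), receptors for interleukin 15 and leukemia inhibitory factor, were also higher, and Cd72 (-2.66), Fam110a (-1.69) and Hspa1b (-3.86) lower, which made 9 genes (4 higher, 5 lower).

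Cholesterol synthesis was the list called both ways. Of 24 members 0 passed over all genes and 5 were lower when adjusted over the list alone (median -0.38, adjusted p = 1.5e-06, adjusted p = 0.018 with an estimated correlation). Cyp51 stood at 58.9 ± 10 CPM in WT and 25.8 ± 5.6 in KO. Homeostatic (2 of 18 lower, Olfml3 and the Cre-bearing Cx3cr1, 8 over the list alone, median -0.52, adjusted p = 1.3e-13), inflammatory (0 of 28, median -0.78, adjusted p = 4.2e-09), ER stress (0 of 15, 3 over the list alone, adjusted p = 6.5e-09) and proliferation genes (0 of 18, 1 over the list alone, adjusted p = 2.1e-05) were lower. None was kept (adjusted p = 0.27 with an estimated correlation for each). Immediate early genes were lower as well (1 of 23, 7 over the list alone, median -1.1, adjusted p = 1.5e-14, adjusted p = 0.32 with an estimated correlation). For LXR targets the median was -0.04 but the mean 0.26 and the test higher, with Apoe as the only member passing (adjusted p = 0.018, adjusted p = 0.32 with an estimated correlation). Ribosomal proteins (median 0.27, adjusted p = 5.5e-12, adjusted p = 0.55 with an estimated correlation) and oxidative phosphorylation (0.16, adjusted p = 0.0098, adjusted p = 0.74 with an estimated correlation) were higher. Astrocyte markers were lower (-1.3, adjusted p = 0.03, adjusted p = 0.32 with an estimated correlation). With WT cisplatin saline 4 as the only WT sample, neither LXR targets (adjusted p = 0.059) nor astrocyte markers (adjusted p = 0.58) were called. The count of 9 fell to 2 without WT cisplatin saline 6 and to 1 without KO cisplatin saline 4 or 5, and rose to 32 without KO cisplatin saline 6. It was 31 without a filter, 22 under a stricter one, 401 by DESeq2, 26 by limma-voom and 0 with the 2 groups alone or sample number as a block. It was 295 with the replicate block, 3 without technical replicate 3, 4 with detected genes as a covariate or without the samples labelled KO cisplatin AIBP, and 0 with the immediate early score as a covariate.

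In WT, AIBP after cisplatin changed no gene past the threshold (0 by edgeR, 759 at an unadjusted p under 0.05, 104 by DESeq2, 4 by limma-voom), with 2 AIBP samples against 3 saline samples. Spp1 stood at 2234 ± 1506 CPM with saline and 921 ± 60 with AIBP, P2ry12 at 1869 ± 798 and 2304 ± 287, and Msr1 at 118 ± 93 and 86.0 ± 10. The 5 smallest p belonged to Il3ra (4.77 ± 3.9 and 0.0948 ± 0.022 CPM), Fmn1 (6.79 ± 1.1 and 0.246 ± 0.21), Ptpn22 (5.12 ± 1.2 and 0.0458 ± 0.0023), Trappc10 (15.3 ± 2.3 and 4.31 ± 1.0) and Nxpe5 (877 counts against 0, at least 180-fold lower). Each had an adjusted p of 0.996. As groups, inflammatory genes (0 of 28, median -1, adjusted p = 7.8e-08), immediate early genes (0 of 23, median -1.2, adjusted p = 2.2e-10), disease-associated genes (0 of 23, median -0.18, adjusted p = 0.023) and monocyte markers (0 of 8, median -2.9, adjusted p = 0.0037) were lower with AIBP. None was kept (adjusted p = 0.61 with an estimated correlation for each). The disease-associated score, as mean log2 CPM above WT naive, was 0.427 and 0.352 with AIBP, 1.19 and 1.41 in WT cisplatin saline 5 and 6, and 0.117 in sample 4. Without samples 5 and 6 which leaves 1 saline sample, the disease-associated (adjusted p = 0.94) and monocyte lists (adjusted p = 0.39) turned to higher and were not called. Tnf stood at 164 ± 91 CPM with saline and 48.3 ± 2.0 with AIBP, and Il1b at 23.8 ± 1.0 and 4.63 ± 0.82. Both were named after their values were seen, and 0 members of these lists passed when adjusted over the list alone. Homeostatic (median 0.26, adjusted p = 0.0015) and interferon genes (0.44, adjusted p = 0.0017) were higher and ribosomal proteins lower (-0.21, adjusted p = 5.9e-09), with adjusted p = 0.71, 0.72 and 0.72 with an estimated correlation. Without samples 5 and 6 the homeostatic (adjusted p = 0.97) and ribosomal protein lists (adjusted p = 0.94) were not called and turned direction, to lower and higher.

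Set against WT naive, the WT cisplatin AIBP samples differed in 256 genes, 217 higher and 39 lower, 214 of them by at least 2-fold. They included C4b (8.17 ± 0.87), Msr1 (5.13 ± 0.95), Mcm2 (3.79 ± 0.66), Mcm6 (3.46 ± 0.53), Cenpk (3.48), Gins2 (3.16), Rpl38 (1.87 ± 0.22) and, among falls, Ptafr (-1.60 ± 0.25), Upk1b (-2.15), H1f0 (-2.12), Lst1 (-2.09) and Rcbtb2 (-1.71). Ribosomal proteins had 36 of 83 higher (67 over the list alone, adjusted p = 9.7e-56, adjusted p = 0.18 with an estimated correlation). Proliferation had 4 of 18 (7 over the list alone, adjusted p = 1.7e-12, adjusted p = 0.1 with an estimated correlation). Cholesterol synthesis, with Cyp51 (1.30) passing and 5 of 24 over the list alone, was called both ways (median 0.79, adjusted p = 9.1e-08, adjusted p = 0.0059 with an estimated correlation). Oxidative phosphorylation (1 of 26, adjusted p = 1.4e-12), ER stress (5 of 15, adjusted p = 1.4e-05), glycolysis (2 of 15, adjusted p = 5.7e-05), interferon (0 of 21, adjusted p = 0.0016) and perivascular macrophage genes (0 of 6, adjusted p = 0.036) were higher. Homeostatic (1 of 18, adjusted p = 9.1e-08) and immediate early genes (0 of 23, adjusted p = 2.4e-07) were lower. None of these 7 was kept (adjusted p = 0.4, 0.57, 0.56, 0.6, 0.57, 0.48 and 0.57 with an estimated correlation). The count was 1 without WT cisplatin AIBP 7, 20 without 9, and 43, 68 and 138 without WT naive 1, 2 or 3, where a lone AIBP sample is assumed to vary like the other groups. It was 603 under a stricter filter, 1353 by DESeq2, 420 with the 2 groups alone, 79 without technical replicate 2, 1142 with the replicate block and 12 with the immediate early score as a covariate.

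In KO after cisplatin, 2 genes differed between the samples labelled AIBP and those given saline. Apoe fell from 12711 ± 7426 CPM with saline to 1312 ± 275 in the samples labelled KO cisplatin AIBP (-3.28 ± 0.32, adjusted p = 0.00112). Cx3cr1 rose from 2235 ± 527 to 5959 ± 980 (1.41 ± 0.19, adjusted p = 0.0201; n = 3 each). Both levels lay within or near the range of the WT samples, 862 to 1898 CPM for Apoe and 5531 to 10656 for Cx3cr1. Esr1, chosen after its values were seen, stood at 42.3 to 85.6 CPM in the KO naive and saline samples, 0.225 to 12.1 in WT and 0.589 to 3.23 in the samples labelled KO cisplatin AIBP (-5.02 ± 1.33 against saline, adjusted p = 0.706).

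Cholesterol synthesis and LXR targets were the lists called both ways. In the samples labelled KO cisplatin AIBP, cholesterol synthesis stood at or near the level of the WT cisplatin samples, as did the LXR target Apoe. Of cholesterol synthesis, 0 of 24 passed over all genes and 5 were higher over the list alone (median 0.54, adjusted p = 3.4e-11, adjusted p = 0.0019 with an estimated correlation). Cyp51 stood at 25.8 ± 5.6 and 71.2 ± 6.2 CPM and Fdft1 at 19.4 ± 6.2 and 43.9 ± 13. Of LXR targets 1 of 14 fell, Apoe, and 2 over the list alone (median -0.37, adjusted p = 1.2e-06, adjusted p = 0.036 with an estimated correlation). Immediate early genes (0 of 23, 10 over the list alone, median 1.4, adjusted p = 1.5e-28, adjusted p = 0.16 with an estimated correlation) were higher, with Hspa1a at 48.9 ± 35 and 438 ± 251 CPM. Also higher were ER stress genes (0 of 15, 5 over the list alone, adjusted p = 1e-09, adjusted p = 0.16 with an estimated correlation) and inflammatory genes (0 of 28, 0 over the list alone, median 0.82, adjusted p = 4.3e-08, adjusted p = 0.2 with an estimated correlation). Homeostatic genes were higher with Cx3cr1 as the only member passing (3 of 18 over the list alone, adjusted p = 3.7e-07, adjusted p = 0.41 with an estimated correlation). Disease-associated genes were lower with Apoe alone passing (2 of 23 over the list alone, adjusted p = 1.2e-06, adjusted p = 0.16 with an estimated correlation). Lysosome genes were lower (median -0.16, adjusted p = 0.027, adjusted p = 0.71 with an estimated correlation) and astrocyte markers higher (0.72, adjusted p = 0.017, adjusted p = 0.25 with an estimated correlation). The next smallest p did not pass: AB124611 at 126 ± 46 and 27.4 ± 2.6 CPM (adjusted p = 0.0553) and Dlec1 at 1.51 ± 0.24 and 0 CPM (347 counts against 0). Counts were 15 without KO cisplatin saline 6, 1 without 4 or 5 or without sample 7 or 9 of those labelled KO cisplatin AIBP. They were 6 without a filter, 185 by DESeq2, 5 by limma-voom, 118 with the replicate block, 1 without technical replicate 1 or 2, and 0 with the 2 groups alone or the immediate early score as a covariate.

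Between genotypes after AIBP, 0 genes passed by edgeR (1299 at an unadjusted p under 0.05, 195 by DESeq2, 12 by limma-voom, 60 with the replicate block). The smallest p belonged to Cd72, an inhibitory receptor, at 176 ± 40 CPM in WT and 23.1 ± 9.6 in the samples labelled KO cisplatin AIBP (-2.93 ± 0.44, adjusted p = 0.185). Next were Cd180 at 147 ± 6.8 and 66.7 ± 3.2 (adjusted p = 0.241), Il3ra (adjusted p = 0.415) and Il15ra at 58.3 ± 3.9 and 162 ± 44 (adjusted p = 0.46). Cd72 had also been lower in KO after saline. Ribosomal proteins (0 of 83, 29 over the list alone, median 0.52, adjusted p = 1.8e-37), immediate early genes (4 of 23 over the list alone, adjusted p = 6.6e-14) and inflammatory genes (adjusted p = 0.00053) were higher in KO. Homeostatic genes were lower (6 of 18 over the list alone, median -0.46, adjusted p = 8.5e-09), as was proliferation (adjusted p = 0.0075). None was kept (adjusted p = 0.72 with an estimated correlation for each). Oxidative phosphorylation (higher, adjusted p = 0.031) and lysosome genes (lower, adjusted p = 0.012) were not kept either (adjusted p = 0.9 with an estimated correlation). The AIBP effect differed between genotypes in 0 genes (1285 at an unadjusted p under 0.05, 136 by DESeq2, 0 by limma-voom, 47 with the replicate block), with Apoe first (-2.54 ± 0.44, adjusted p = 0.774).

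Whether AIBP turned the cisplatin changes back was read across genes. In WT the fold changes of cisplatin and of AIBP had r = -0.426 over 20461 genes, against -0.443 (-0.457 to -0.423) in simulations with no effect, since both contrasts share the saline samples. Over 8570 genes at 10 CPM or more, r was -0.245 against -0.443, and the covariance -0.0769 against -0.0793. In KO, r was -0.457 against -0.5 (-0.516 to -0.481), and at 10 CPM or more -0.446 against -0.505 with a covariance of -0.154 against -0.0806. Apoe and Cx3cr1 were the genes called in opposite directions by cisplatin and AIBP in KO. Independent lists would share 0.0242 and 0.0199, but these contrasts share the KO cisplatin saline samples, which favours opposite calls. That expectation therefore does not apply, and both genes lay within or near the WT range in the samples labelled KO cisplatin AIBP. The AIBP effects in WT and KO, which share no samples, had r = -0.0288 (-0.0239 at 10 CPM or more). The cisplatin effect and the naive knockout effect, which share the WT naive samples, had r = 0.518 against 0.504 (0.486 to 0.526) in simulations, and 0.404 against 0.502 at 10 CPM or more, with C4b called in both. Their covariance lay above the simulated mean, at 2.69 against 1.58, and at 0.122 against 0.0802 at 10 CPM or more.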

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

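The matching on transcript length, GC content and expression was laid down before its result was seen; the other tests of explanations and the regroupings of samples below were chosen after the results were seen.

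Gene lists differed between genotypes in their response to cisplatin by a test of the difference itself, KO minus WT (camera, BH over 30 lists). They were lower for homeostatic (adjusted p = 1.5e-05, median log2 difference -0.40, 3 of 18 lower when adjusted over the list alone), disease-associated (0.017, median -0.25), cholesterol synthesis (0.012, -0.35), inflammatory (1.2e-05, -0.78), interferon (3.2e-08, -1.5), antigen presentation (0.011, -0.31), ER stress (0.00041, -0.59), immediate early (4.3e-10, -0.81) and proliferation genes (1.2e-10, -1.7) and for perivascular macrophage markers (0.023, -6.0). Oxidative phosphorylation was higher (0.011, median 0.17). In their response to AIBP, inflammatory (adjusted p = 1.9e-14, median 1.9, 9 of 28 over the list alone), immediate early (2.1e-35, 2.6, 22 of 23), cholesterol synthesis (0.0014, 0.34), ER stress (4.1e-05, 0.52) and ribosomal protein genes (1.4e-05, 0.25) were higher in KO, and LXR targets (0.025, -0.35) and lysosome genes (0.025, median -0.28 but mean 0.21) lower. No list of either set was kept with an estimated correlation, where the smallest adjusted p was 0.17, and 0 single genes passed in either interaction. Without WT cisplatin saline 5 and 6, where monocyte transcripts stood high, 1 sample is left in that group, and the calls of disease-associated (adjusted p = 0.88), antigen presentation (0.77), ER stress (0.23) and perivascular macrophage genes (0.79, turned to higher) ended in the response to cisplatin, and those of ER stress (0.22), lysosome (0.062) and ribosomal protein genes (0.89) in the response to AIBP.

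Ribosomal protein and oxidative phosphorylation lists were higher after cisplatin in both genotypes by camera with its preset correlation, with 0 members lower (adjusted p = 0.072 and 0.24 in WT and 0.13 for each in KO with an estimated correlation). Fold changes ran with transcript length (Spearman -0.28 in WT and -0.25 in KO across genes), and ribosomal protein transcripts are short (median 942 bases against 3011), yet the highest median of 2000 random lists matched on length, GC content and expression was 0.58 in WT and 0.69 in KO, below the lists' 1.1 and 1, which argues against this trend as the whole cause. For oxidative phosphorylation the same holds in KO (highest 0.75 against 0.82), while in WT the highest was 0.67 against 0.64, with 2 of 2000 as high; with the trend taken out, ribosomal protein medians were 0.71 and 0.64 and 41 and 40 members passed (62 and 59 before), and for oxidative phosphorylation 0.42 and 0.59 with 4 and 11 (8 and 13 before). Transcripts of monocytes stay open for both lists: of the 6 cisplatin saline samples only WT cisplatin saline 4 had a monocyte score within the naive range, and its scores of 0.808 and 0.429, above the naive highest of 0.389 and 0.197, come from 1 biological sample. Samples given AIBP were not part of this check. In WT AIBP against WT naive both lists were called higher with the preset correlation. There the monocyte list was not called, which does not show that monocyte transcripts were absent, and perivascular macrophage markers were. A response of microglia to cisplatin or to the injection may also account for the rise, and the design cannot separate these 2.

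Cx3cr1, Apoe and Esr1 of the samples labelled KO cisplatin AIBP lay at the WT level. Cholesterol synthesis, as mean log2 CPM above WT naive, stood at 1.16 to 1.21 in them. It stood at 0.66 to 1.23 in the WT cisplatin samples and at -0.0412 to 0.324 in KO cisplatin saline. The LXR target list, which holds Apoe, summed to 1709 to 2156 CPM, against 1726 to 2760 and 8971 to 22102. Apoe made up most of the sum in KO cisplatin saline (21278 of 22102 CPM in sample 4), so the sum largely repeats Apoe. As mean log2 CPM above WT naive, LXR targets stood at -0.684 to -0.00363, against -0.483 to 0.667 and 0.334 to 0.68. Cholesterol synthesis thus also lay at or near the WT cisplatin level. The LXR score did not separate KO cisplatin saline from WT cisplatin. A swap with WT samples is argued against, with limits, by 12 other genes that separate the genotypes in the naive and saline samples. On a scale from 0 at WT to 1 at KO, the lowest of the 3 samples had a median position of 0.72. The WT AIBP samples had 0.21 and 0.35. These genes are not 12 independent markers, and some may separate by chance. Mid1, G530011O06Rik and Gm15726 share an end of the X chromosome (means 1 to 1.2 against 0.26 to 0.57 in WT AIBP). Gm4951, Trim30b and Plpp6 did not separate the AIBP groups (0.83, 0.55 and 0.54 against 0.76, 0.63 and 0.56). Ddit4 also stood higher in KO cisplatin saline than in KO naive. That these samples carry no Cre allele would account for Cx3cr1 and Esr1 and stays open. Cx3cr1-CreERT2 alleles commonly replace a copy of Cx3cr1, and Esr1 reads may come from the estrogen receptor part of CreERT2. The highest Esr1 level of the 3 samples was 3.23 CPM against a lowest of 42.3 in the other KO samples. A missing allele would account for Apoe only if the allele or the deletion raises Apoe in the other KO samples, which was not tested. If Esr1 reads come from CreERT2, an effect of AIBP on the Cx3cr1 promoter that drives it would move Cx3cr1 and Esr1 the same way. They went apart: Cx3cr1 stood at 5250 to 7078 CPM against 1718 to 4871 in the other KO samples, while Esr1 was lower. On that condition, these values argue against an effect through this promoter. Separate effects of AIBP on Cx3cr1, Apoe and Esr1 (Esr1 log2 fold change -5.02) cannot be told apart from a missing Cre allele. AIBP was given to all 3 samples, and no KO sample with AIBP had the Esr1 of the other KO samples. In WT, Apoe stood at 862 and 1073 CPM with AIBP against 1405 to 1898 with saline. Cx3cr1 stood at 7297 and 7902 against 5531 to 7103, and neither gene passed. If the Cre allele is missing, every comparison with these samples compares mice without the deletion, on which the AIBP effect in KO, the knockout effect after AIBP and the genotype difference in the AIBP effect rest.

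Inflammatory and immediate early genes were lower with AIBP in WT and higher in the samples labelled KO cisplatin AIBP by camera with its preset correlation (with an estimated correlation, adjusted p = 0.61 for each in WT, and 0.2 and 0.16 in KO). A response to cell isolation stays open: taken as deviations from group means over 17 samples, the scores of the 2 lists, which share 0 genes, had r = 0.814 and rho = 0.77 (exact permutation p = 0.0015 and 0.0026, two-sided, 15552 permutations, adjusted p = 0.003 over the 2 relations tested), and r = 0.703 without the 2 samples farthest in the immediate early score. Transcripts of monocytes in WT cisplatin saline were looked at too: the monocyte score had r = 0.169 and rho = 0.199 with the inflammatory score (exact permutation p = 0.47 for each, adjusted p = 0.47, r = 0.214 without the 2 farthest). The inflammatory score was 1.13 in WT cisplatin saline 4, whose monocyte score lay within the naive range, and 1.14 and 1.13 in samples 5 and 6, where monocyte transcripts stood high. This argues against monocytes as the source of the level in sample 4. It is 1 biological sample, so monocytes stay open for samples 5 and 6. The inflammatory list was also lower with AIBP with samples 5 and 6 left out, where 1 saline sample is left. An effect of AIBP on inflammatory genes is the biological explanation the design names, and it was not tested apart from these.

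Regrouping the samples tests whether chance in the grouping gives as many genes. The 10 splits of 6 samples into 3 and 3 are too few for a share under 0.05 (the smallest is 0.1); the real counts and the highest of the other splits were 595 and 1 for cisplatin in WT, 1 and 1 for the knockout in naive samples, 903 and 0 for cisplatin in KO, 2 and 0 for AIBP in KO, and 9 and 0 for the knockout after saline. For the genotype difference in the cisplatin effect, the real count was 0, which all 40 regroupings of 12 samples must reach (highest 2), so this count says nothing about chance.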

How the results depend on the processing

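The length and GC offset, 51 libraries or 102 runs as independent samples, the normalized table's genes, the fit without the samples labelled KO cisplatin AIBP, WT cisplatin saline 5 and 6 left out and the immediate early covariate were chosen after the data were seen. Counts of called genes depended strongly on the setting, and the cause was not tested unless stated. Below, cisplatin WT and KO, AIBP WT and KO, KO naive, KO saline, KO AIBP and WT AIBP to naive stand for the 8 contrasts, with counts as reported of 595, 903, 0, 2, 1, 9, 0 and 256, and the cisplatin and AIBP interactions for 0 and 0.

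With 1 sample left out the ranges were 149 to 853 (cisplatin WT), 366 to 788 (cisplatin KO), 0 to 2 (AIBP WT), 1 to 15 (AIBP KO), 0 to 2 (KO naive), 1 to 32 (KO saline), 0 to 0 (KO AIBP), 1 to 138 (WT AIBP to naive), 0 to 6 (cisplatin interaction) and 0 to 0 (AIBP interaction). With RLE scaling KO naive was 2. Without a filter KO naive was 5, AIBP KO 6, KO saline 31, KO AIBP 1 and the interactions 6 and 1. A stricter filter, which tests 10835 genes, gave cisplatin WT 977, cisplatin KO 1389, KO naive 4, KO saline 22, KO AIBP 1, WT AIBP to naive 603 and the cisplatin interaction 3. DESeq2 gave 1795, 2193, 104, 185, 170, 401, 195 and 1353 in the order of the contrasts above, and 187 and 136 for the interactions. limma-voom gave AIBP WT 4, AIBP KO 5, KO saline 26, KO AIBP 12 and the cisplatin interaction 1. A fit of the compared groups alone gave cisplatin WT 69, cisplatin KO 584, WT AIBP to naive 420, and 0 for KO naive, AIBP KO and KO saline.

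With technical replicates as libraries (their correlation 0.0893) and no replicate block, cisplatin WT was 1787, cisplatin KO 2401, AIBP KO 135, KO naive 15, KO saline 322, KO AIBP 67, WT AIBP to naive 1096 and the interactions 37 and 49; with their number as a replicate block these were 1840, 2356, 118, 16, 295, 60, 1142, 47 and 47. Sample number as a replicate block between genotypes gave 0 for KO naive and KO saline. Neither number marked a pairing: same-numbered WT and KO samples had r of -0.137 to 0.145 across genes. Without technical replicate 1, AIBP KO was 1. Without 2, cisplatin WT was 287, cisplatin KO 526, AIBP KO 1 and WT AIBP to naive 79. Without 3, cisplatin WT was 381, KO naive 0 and KO saline 3. The share of genes detected as a covariate gave KO saline 4. Each lane alone, the length and GC offset and the normalized table's genes left the count of called genes of each contrast within 1.5 times. Under the offset the genes changed more than their count: 426 of the 595 called for cisplatin WT stayed called. Of the list calls, 71 were kept, 20 were lost and 1 was lost with its direction turned.

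Taken as independent, which ignores that replicates share a sample, 51 libraries gave cisplatin WT 2378, cisplatin KO 2659, AIBP KO 145, KO naive 43, KO saline 503, KO AIBP 145, WT AIBP to naive 1686 and interactions 176 and 117. The 102 runs gave 4814, 5224, 760, 1628, 1201, 2526, 1877 and 4370 in the order above, and 1624 and 1187. Without the samples labelled KO cisplatin AIBP, KO saline was 4. Without WT cisplatin saline 5 and 6 (1 sample left), cisplatin WT was 7 and KO saline 1. With the immediate early covariate, cisplatin KO was 95, AIBP KO 0, KO naive 3, KO saline 0, KO AIBP 2 and WT AIBP to naive 12.

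Of 92 list calls over the contrasts, 5 were kept with an estimated correlation, a test run on log2 CPM and not on the counts. The camera test was not run under DESeq2. The inflammatory list after cisplatin in KO turned higher with the immediate early covariate (adjusted p = 0.02), and Clec4n in cisplatin WT had -0.30 without samples 5 and 6. Over 39 settings, single lists kept their call in 2152 values, lost it in 345 and, with the direction turned, in 10 more, and named genes kept their side of the threshold in 7442, with 966 losing and 740 gaining a call and 7 turning sign without a call in either setting. Correlations across genes kept their sign: leaving out 1 sample gave 0.471 to 0.634 (cisplatin WT with KO naive), -0.503 to -0.386 and -0.586 to -0.363 (reversal in WT and KO), 0.0978 to 0.138 (cisplatin WT with KO) and -0.051 to -0.00585 (AIBP WT with KO). Reversal in WT was -0.284 under the stricter filter and in KO -0.657 with the immediate early covariate. Cisplatin WT with KO was 0.0753 without a filter, 0.516 under the stricter one and 0.233 by limma-voom, and AIBP WT with KO -0.0723 under the stricter filter and -0.266 with the covariate. Depth limits genes near 0 CPM, where a group held 0 to 3 counts. The spread between summed samples, which includes technical spread, limits the calling of changes of about 2-fold where few genes change.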

Other observations

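The genes of this paragraph were chosen after their values were seen, and no list of them was tested. Fkbp5, the immunophilin of the glucocorticoid receptor complex, stood at 150 to 245 CPM in KO cisplatin saline and 133 to 232 in the samples labelled KO cisplatin AIBP, against 72.7 or less in KO naive and 114 or less in WT. Tsc22d3, which encodes GILZ, stood at 508 to 627 CPM in KO cisplatin saline and 262 to 561 in the samples labelled KO cisplatin AIBP, against 103 to 416 and 87.3 to 106 in the WT groups with saline and AIBP, 370 to 477 in WT naive and 134 to 448 in KO naive. The clock gene Per1 stood at 72.9 to 220 and 66.2 to 130 CPM in these KO groups and at 71.2 or less in WT and 67.2 or less in KO naive. Klf9 (4.82 ± 1.29, adjusted p = 0.048) and Il1r2 (6.16 ± 1.60, adjusted p = 0.041) rose after cisplatin in KO, by edgeR, to 8.29 to 113 and 8.31 to 243 CPM. They stood at 3.56 to 5.11 and 0.635 to 8.44 in the samples labelled KO cisplatin AIBP. Fkbp5 (adjusted p = 0.12), Per1 (0.12), Ddit4 (0.13), Zbtb16 (0.28) and Tsc22d3 (0.34) did not pass for cisplatin in KO. Ddit4 stood at 14.2 to 33.6 CPM in KO cisplatin saline, 11.7 to 18.7 in the samples labelled KO cisplatin AIBP, 2.44 to 6.94 in KO naive and 1.62 or less in WT. Sgk1 and Cdkn1a, looked at with them, did not follow: Sgk1 stood at 281 to 439 CPM in KO cisplatin saline and 552 to 888 in KO naive, and Cdkn1a at 163 to 272 and 138 to 318. No interaction of these genes passed (Klf9 adjusted p = 0.61). Between KO and WT after cisplatin and saline none passed either, by edgeR. Adjusted p was 0.15 for Ddit4, 0.27 for Il1r2, 0.34 for Klf9, 0.42 for Per1, 0.43 for Fkbp5 and 0.48 for Tsc22d3.

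Transcripts of monocytes and border macrophages varied among samples of the same group. Fn1 stood at 236, 874 and 563 CPM in WT cisplatin saline 4, 5 and 6, at 639 to 1088 in KO cisplatin saline and at 652 in sample 8 of those labelled KO cisplatin AIBP. Chil3 stood at 49.4 and 44.8 CPM in WT cisplatin saline 5 and 6, 116, 106 and 76.9 in KO cisplatin saline and 102 in that sample 8. Ms4a7 was seen at 15.9 and 14.2 CPM in WT cisplatin saline 5 and 6 and 17.2 in WT cisplatin AIBP 9, and Pf4 at 40.6 and 31.6 CPM in WT cisplatin saline 5 and 6 and 25 in sample 8 of those labelled KO cisplatin AIBP. Ly6c2 stood at 7.90 and 13.9 CPM in WT cisplatin saline 5 and 6 and at 6.49 in KO cisplatin saline 4. Sample 8 thus stood apart from 7 and 9 of its group, with Clec4n at 55.2 CPM.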
